A study of Homo sapiens with 24 samples.

How the data were processed

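The arrays are 2-colour oligonucleotide arrays made of 2 chips each. The samples are 24 hybridizations, 4 kinds of comparison with 3 replicate numbers and both dye orientations. Each dye-swapped pair of arrays was averaged into 1 value, so every comparison has n = 3 and 12 pairs enter the fit. The labels do not say whether the replicate numbers stand for separately grown cultures, so the p-values measure only the spread between these samples. The cells are U937, an established human monocytic line, as transfected pools. Secreted TNF and quantitative PCR of the unfolded protein response are named in the design text and were not analysed here.

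The deposited files hold, per the file headers, the amplitude of each channel for each of 21120 spots per chip, an intensity that BlueFuse estimated with a model and that is above 0 for every spot. Per the file headers, BlueFuse 2.0 was used, build 2926 for chip 1 and build 3276 for chip 2. A confidence, given by the authors as a fraction, comes with each spot. The deposited value table holds 18665 unnamed lines of the natural log of the channel 1 over channel 2 ratio. That scale and direction are not stated and were found by setting the table against the amplitudes of the same arrays. How the authors combined spots into that table is not given in the sources used here. GeneSpring 7.2 with loess and the methods' t-test at the 95% level is named by the authors, per the labels. The channel 1 colour was the dye of the numerator RNA in 48 of 48 files, and 0 spots had been excluded by hand. Amplification by template-switching PCR, named in the labels, can narrow or widen ratios between transcripts, which was not measured here. A ratio of amplitudes also shrinks towards 0 when a spot nears background or saturation. The number of arrays limits the precision.

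For the main analysis the log2 ratio of the amplitudes was taken with no further background correction, since the amplitudes come from a model. Each chip of each array was normalized with a global loess (span 0.3, 4 iterations). Control and empty spots were left out, and spots of the same probe were averaged. A gene was represented by the probe with the highest mean log2 amplitude over all arrays, chosen without the contrasts, and a probe with no gene symbol stayed a feature of its own. This gave 18547 features. Of 18665 library probes, 8324 were named by accession, 365 by a symbol in the file's own description, 468 by an older symbol there and 14 by a written-out description, and 9494 stayed unnamed. A symbol in a description that now belongs to another gene was not used. That check was added after the values had been seen, when a galectin probe carried the older symbol GRIP1, and the probe is called LGALS12 here. No probe was named for CXCL8, HLA-B, HLA-C, HLA-E or HLA-G, which were therefore not analysed here. An antisense transcript among the 10 largest falls of B27+LPS over C could be matched by an older symbol only, and its value is not given.

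The pair means were fitted with limma 3.58.1 in R 4.3.3, with 1 mean for each of the 4 kinds of array and a moderated error shared between them. The LPS response in B27 cells was tested as B27+LPS over C minus B27 over C, and the interaction as B27+LPS over C+LPS minus B27 over C. Errors given after ± are the standard errors of that fit, and adjusted p-values are Benjamini-Hochberg over all features, with the threshold at 0.05. Genes that passed had the same sign in 3 of 3 replicates in every comparison. Genes were named by a rule written before the data were seen. It takes the 10 largest rises and 10 largest falls among genes past the threshold with the same sign in 3 replicates, or, where fewer than 5 passed, the 5 smallest p-values as values without a call. It adds the 4 members with the smallest p of each list that had at least 2 called members or passed its own test. It always adds TNF, IL6, IL10, CXCL8, IL1B, TLR4, CD14, HLA-B, B2M, HSPA5, XBP1, DDIT3 and ATF4 where measured. The probes of ATF4 and NOL3 were not well above the empty spots in the comparisons against C, nor was VPS9D1 in B27 over C.

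The gene lists were fixed before the data were seen. They are ER chaperones, folding enzymes and ERAD (25 members measured), the PERK and ATF4 arm with amino acid stress (18), MHC class I presentation (8), inflammatory cytokines and chemokines (30), NF-kB targets and feedback regulators (33), interferon-stimulated genes (36), LPS receptor and proximal signalling (16), macrophage differentiation markers (30), myeloid progenitor genes (12), cell cycle (29), cytosolic heat shock proteins (11), oxidative stress and metallothioneins (12), cholesterol biosynthesis (16), hypoxia and glycolysis (20), ribosomal proteins as a check of RNA quality (21), and markers of T cells (11), B cells (8), epithelial cells (10), fibroblasts (5) and erythroid cells (7). MHC class II presentation had 1 measured member and was not tested. Lists were tested with camera at a preset correlation of 0.01, 120 tests adjusted together, and again with an estimated correlation. The 6 calls that hold with an estimated correlation are those of the cytokine and NF-kB lists in C+LPS over C, B27+LPS over C and the LPS response in B27 cells. fry was run beside camera, and it tests whether the members of a list changed as a group without setting them against the other genes. In fry the cytokine list had adjusted p = 2.46e-07 and the NF-kB list 6.21e-06 in C+LPS over C.

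Simulated arrays kept the mean amplitude of each spot, and their ratios were built anew. These ratios held a set intensity curve, a random dye effect, random noise scaled to the error of each probe, and known changes. The noise was drawn separately for each probe and replicate, so it held no deviation shared between genes or comparisons. The shares that follow are therefore for an idealized case. At a log2 change of 1, 95.5% of changed genes were recovered for B27 over C, 89.2% for C+LPS over C, 85.1% for B27+LPS over C, 86.6% for B27+LPS over C+LPS, 75.9% for the LPS response in B27 cells and 79.3% for the interaction. At 0.5 the shares ran from 17.9% to 44.8%. Calls with no simulated change made up 3.77% to 7.27%, and 0 of 114 tests of unshifted lists passed. In the simulation the members of a list could not vary together. In the data the estimated correlations were 0.10 for the cytokine, 0.11 for the NF-kB and 0.14 for the interferon-stimulated list. The 0 of 114 therefore cannot show how the preset correlation serves lists whose members vary together.

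The replicate numbers pair the 3 comparisons against C. After the group means were removed, same-number correlations between these comparisons ran from 0.249 to 0.535, over 0.1 in 9 of 9, against 0.0188 to 0.203 with B27+LPS over C+LPS, over 0.1 in 3 of 9. The same number gave the highest correlation in 8 of 9 in both sets, so the pairing with B27+LPS over C+LPS is weaker but not absent. Per the file headers the arrays against C of 1 replicate number share a scan day on each chip, and all chip 1 arrays of B27+LPS over C+LPS were scanned on another day. The chip 2 arrays of B27+LPS over C+LPS carry no scan day, and the chip 2 arrays of replicate 6 against C were scanned on the day of those chip 1 arrays. The interaction thus sets arrays of different days against each other on chip 1, and on chip 2 this is not known. Within a day each comparison against C has 1 replicate, which is the replicate value. A block for replicate or day takes the replicates' shared deviation out of the error of a ratio tested against 0, so it can raise counts by construction. In the difference of 2 comparisons against C that shared deviation cancels, and the block acts there as a pairing. The scan-day block is the replicate block applied to the arrays against C only. It has no term for the day of B27+LPS over C+LPS, so it does not adjust the interaction for scan day. Across features the log2 ratios of the 2 arrays of a pair correlated from -0.509 to 0.561. In replicates 6, 8 and 9 the values were -0.248, -0.192 and -0.509 for B27 over C. They were 0.118, -0.124 and -0.043 for B27+LPS over C+LPS, and ran from -0.207 to 0.561 for the LPS arrays against C. The dye-swapped arrays thus did not agree in the 2 direct B27 comparisons. A dye effect past the threshold was found for 2675 features, which the pair mean cancels to first order. In each orientation the 36 correlations between arrays against C were above 0. On 1 chip of B27+LPS over C+LPS only 33.7% of numerator spots lay above the 95th percentile of the empty spots, and on 1 chip of C+LPS over C 18.4% did, where the empty spots were bright.

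The alternatives were chosen before the data were examined, except those named in the closing section. They were median centring, print-tip loess, an offset of 50, dim probes left out, the 25% of spots with the lowest confidence left out, arrays scaled to equal spread, the authors' value table, the methods' t-test, only the comparison's own arrays, a model of the RNA sources, 24 arrays with a dye term, a replicate block, each replicate left out, each dye orientation alone (for single features, not for the lists), all probes as features, and an estimated correlation for the lists.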

Results

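U937 cells, a human monocytic line, carried either HLA-B27, the class I molecule linked to spondyloarthritis, or plasmid alone (C). Per the labels, the transfected pools were differentiated with PMA at 10 ng per ml for 24 h and then cultured for 4 h with or without LPS at 500 ng per ml. RNA was compared on 24 two-colour arrays. B27, C+LPS and B27+LPS were each set against C, and B27+LPS was set directly against C+LPS. Each comparison had 3 replicates, and each replicate was a dye-swapped pair of arrays.

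In control cells given LPS, genes of chemokines and cytokines were among the largest rises. SOD2, the mitochondrial superoxide dismutase, rose by 4.89 ± 0.12 log2 (29.7-fold, n = 3), and the chemokines CCL4 by 4.73 ± 0.10, CCL1 by 4.47 ± 0.34, CCL20 by 4.06 ± 0.10, CCL8 by 3.77 ± 0.21 and CXCL10 by 3.48 ± 0.17. The cytokine gene IL1B rose by 3.95 ± 0.23, the matrix metalloproteinase gene MMP3 by 3.57 ± 0.23, and CD274, which encodes the checkpoint ligand PD-L1, by 3.54 ± 0.27. SERPINB2, an inhibitor of plasminogen activators, rose by 3.32 ± 0.64 with replicate values from 1.81 to 5.18. TNF rose by 2.28 ± 0.22 (adjusted p = 9.20e-05), IL6 by 2.07 ± 0.25 and IL10, an anti-inflammatory cytokine, by 3.17 ± 0.13. The largest falls were those of GPR34, a G protein-coupled receptor (-2.35 ± 0.24), EVI2B, a membrane protein of blood cells (-2.23 ± 0.21), the galectin gene LGALS12 (-1.76 ± 0.30) and CD244, a receptor of the SLAM family (-1.68 ± 0.20). ADORA3, an adenosine receptor, fell (-1.50 ± 0.25), as did the adaptor SLA (-1.37 ± 0.24), the oxysterol receptor GPR183 (-1.27 ± 0.19), the tyrosine phosphatase PTPN22 (-1.24 ± 0.13), the myeloid transcription factor CEBPA (-1.23 ± 0.30) and KBTBD11 (-1.23 ± 0.19). Adjusted p-values of these genes ran from 5.35e-10 for CCL4 to 0.0356 for CEBPA.

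Of 30 measured cytokine and chemokine genes 23 rose and 7 did not pass in C+LPS over C (26 rose adjusted over the list alone). The list's median was 1.90 (adjusted p = 2.42e-40, and adjusted p = 0.00214 with an estimated correlation). CCL3 rose by 3.27 ± 0.18, CCL5 by 2.07 ± 0.13, CSF2, a colony-stimulating factor, by 1.60 ± 0.18, and PTGS2, the inducible cyclooxygenase, by 2.53 ± 0.22. These 4 were picked from the list after their values were seen. Of 33 NF-kB targets 16 rose and 17 did not pass (21 rose adjusted over the list alone), with a median of 0.56 (adjusted p = 1.38e-20, and adjusted p = 0.0184 with an estimated correlation). Beside SOD2, the adhesion molecule ICAM1 rose by 2.02 ± 0.09, the signalling adaptor TRAF1 by 1.76 ± 0.13 and GADD45B, a stress-response gene, by 1.10 ± 0.10. Of 36 interferon-stimulated genes 11 rose and 25 did not pass (18 rose and 1 fell adjusted over the list alone). The median was 0.26 (adjusted p = 7.05e-10, but adjusted p = 0.199 with an estimated correlation, and fry adjusted p = 0.00521). SP110 rose by 0.62 ± 0.08, the antiviral genes IFIT1 by 1.03 ± 0.14 and EIF2AK2 by 0.67 ± 0.09, and USP18, which removes ISG15 from proteins, by 0.71 ± 0.11.

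Among 25 ER chaperone, folding and ERAD genes 3 rose in C+LPS over C, 0 fell and 22 did not pass (4 rose adjusted over the list alone, list adjusted p = 0.215). They were XBP1, a transcription factor of the unfolded protein response (0.56 ± 0.10, adjusted p = 0.00594), the co-chaperone DNAJC3 (0.42 ± 0.09) and the oxidase ERO1B (0.35 ± 0.09). SEC61B, part of the translocon, stood at 0.53 ± 0.15 (adjusted p = 0.0670) and HSPA5, the chaperone BiP, at 0.30 ± 0.21. In the PERK and ATF4 arm only ATF3 of 18 genes rose (2.67 ± 0.15, adjusted p = 1.88e-06, chosen after its value was seen). That list's median was -0.06 and its mean 0.13 (adjusted p = 0.910), and DDIT3, or CHOP, stood at -0.06 ± 0.23 and ATF4 at 0.10 ± 0.09. Of 8 class I presentation genes B2M, the class I light chain, rose (0.63 ± 0.14, adjusted p = 0.0209, list adjusted p = 0.954). Of 16 LPS receptor and signalling genes only TLR2 rose (1.50 ± 0.17, chosen after its value was seen, list adjusted p = 0.712), while TLR4, the LPS receptor, stood at 0.08 ± 0.12 and its co-receptor CD14 at 0.07 ± 0.09.

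Of 30 macrophage markers 4 rose in C+LPS over C and 1, CEBPA, fell, with 25 not passing (the same numbers adjusted over the list alone, list adjusted p = 0.910). The 4 were the elastase MMP12 (1.98 ± 0.21), the haemoglobin scavenger receptor CD163 (1.73 ± 0.25), and the calcium-binding S100A9 (1.41 ± 0.21) and S100A8 (0.59 ± 0.12). Of 12 oxidative stress genes and metallothioneins the metallothionein genes MT2A (1.98 ± 0.21) and MT1G (0.70 ± 0.16) and the reductase gene TXNRD1 (1.12 ± 0.22) rose, and HMOX1, haem oxygenase, fell (-0.75 ± 0.19). 8 of that list did not pass (4 rose and 1 fell adjusted over the list alone, list adjusted p = 0.0863). Of 20 hypoxia and glycolysis genes PFKFB3, a regulator of glycolysis, rose by 1.70 ± 0.10, the peptide hormone gene ADM by 0.57 ± 0.07, the aldolase ALDOC by 0.33 ± 0.06 and the glucose transporter SLC2A3 by 0.44 ± 0.09 (16 did not pass, 4 rose adjusted over the list alone, list adjusted p = 0.107). Of 16 cholesterol genes SREBF2 (0.50 ± 0.09) and INSIG1 (1.29 ± 0.26), which regulate sterol synthesis, rose, HMGCS1 stood at 0.40 ± 0.11 and FDFT1 at -0.52 ± 0.16. The median of that list was -0.10, its mean 0.00 and its test pointed down (adjusted p = 0.910, 3 rose and 2 fell adjusted over the list alone). Of 29 cell cycle genes the cyclin CCNE2 (0.64 ± 0.12) and the inhibitor CDKN1A (0.79 ± 0.19) rose, PLK1, a mitotic kinase, fell (-0.84 ± 0.21), and TOP2A stood at -0.30 ± 0.08 (26 did not pass, 2 rose and 3 fell adjusted over the list alone, list adjusted p = 0.215).

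Of 12 myeloid progenitor genes 0 passed in C+LPS over C (3 fell adjusted over the list alone, median -0.14, adjusted p = 0.215). The co-chaperone DNAJB1 (-0.49 ± 0.10) was the only called member of 11 cytosolic heat shock genes (list adjusted p = 0.954), and CD28, at 0.42 ± 0.10, the only called member of 11 T cell markers (list adjusted p = 0.191). Both were chosen after their values were seen. 0 of 21 ribosomal protein genes (adjusted p = 0.910, median -0.03, mean 0.04), 8 B cell (0.853), 10 epithelial (0.876), 5 fibroblast (0.703) and 7 erythroid markers (0.891) passed. By fry the oxidative stress list (median 0.35) and the hypoxia list (median 0.03) passed in C+LPS over C, each with adjusted p = 0.00244. With replicate number as a block the oxidative stress list had camera adjusted p = 0.0197. Without replicate 8 it had 0.0362 and the cell cycle list 4.26e-04, and without replicate 6 the ER list had 0.0435.

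In all, 1060 of 18547 features passed in C+LPS over C, 714 up and 346 down (67.4% up), and 203 changed by over 1 log2. With the pairing of replicates as a block 1695 passed. The count was 187 without replicate 6 and 366 without replicate 9, 132 with only the comparison's own arrays and 0 with the methods' t-test after the same adjustment. Of 51 genes named here that passed, 25 kept their call whichever replicate was left out, among them SOD2, CCL4, IL1B, IL10, TNF and IL6.

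**Figure D1:**
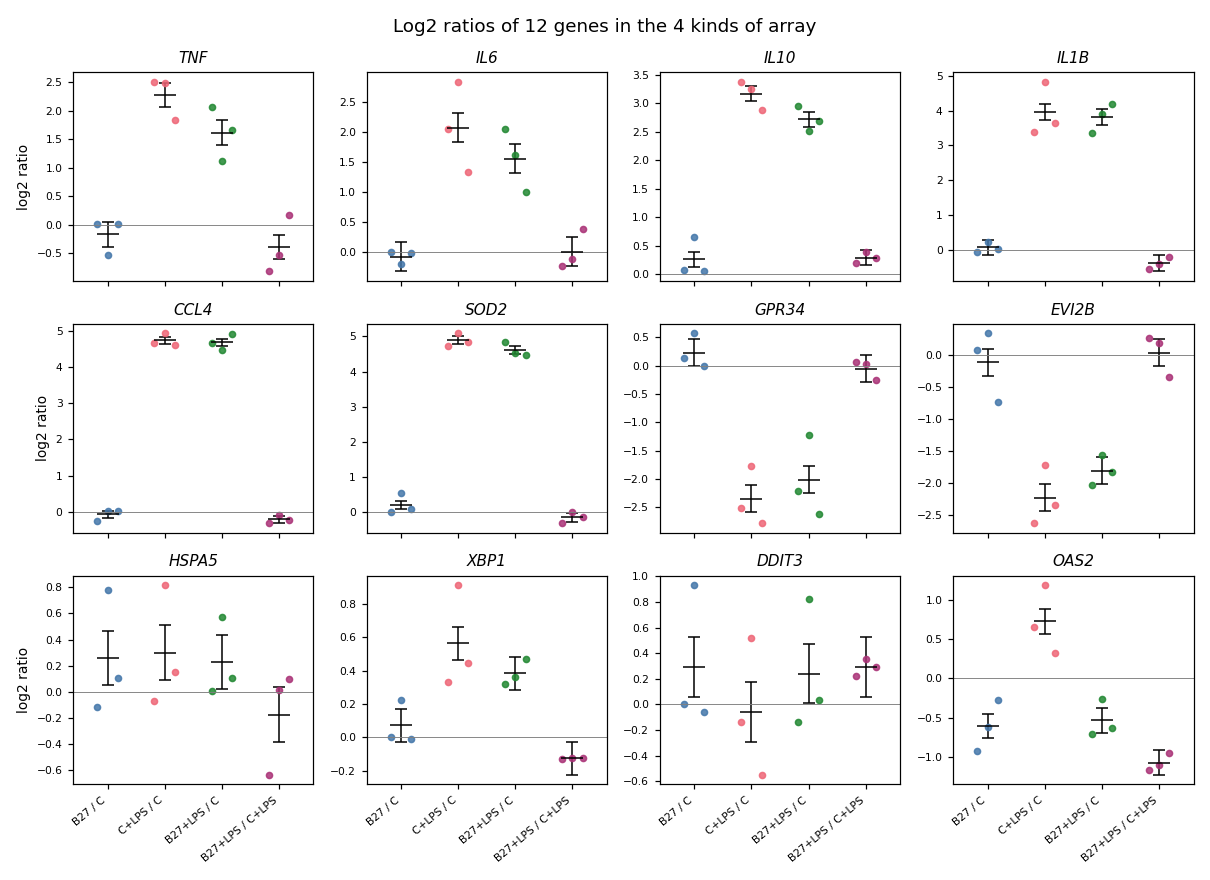
Log2 ratio of 12 genes in the 4 kinds of array. Each dot is 1 replicate (a dye-swapped pair), horizontal bars are means of 3 and error bars are standard errors of the limma fit. CCL4 lies near 4.73 in C+LPS over C and 4.68 in B27+LPS over C, and OAS2 at -1.07 in B27+LPS over C+LPS without passing the test.

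In B27 cells given LPS, set against untreated control cells, chemokine genes were again among the largest rises. CCL4 rose by 4.68 ± 0.10, SOD2 by 4.62 ± 0.12, IL1B by 3.81 ± 0.23, CCL8 by 3.76 ± 0.21, CCL1 by 3.70 ± 0.34, CCL20 by 3.41 ± 0.10, CCL3 by 3.09 ± 0.18 and CXCL10 by 2.98 ± 0.17 (log2, n = 3). SERPINB2 rose by 2.96 ± 0.64 and MMP3 by 2.89 ± 0.23. TNF rose by 1.62 ± 0.22 (adjusted p = 0.00173), IL6 by 1.55 ± 0.25 and IL10 by 2.72 ± 0.13. GPR34 fell (-2.02 ± 0.24), as did EVI2B (-1.80 ± 0.21), LGALS12 (-1.58 ± 0.30), OGG1, a DNA repair glycosylase (-1.38 ± 0.20), KBTBD11 (-1.36 ± 0.19), CD244 (-1.30 ± 0.20), GPR183 (-1.23 ± 0.19), SLA (-1.03 ± 0.24) and the transcriptional regulator LMO1 (-0.99 ± 0.20). Adjusted p-values ran from 5.97e-10 for CCL4 to 0.0459 for SLA. B2M stood at 0.47 ± 0.14 (adjusted p = 0.103), XBP1 at 0.38 ± 0.10 (adjusted p = 0.0611), HSPA5 at 0.23 ± 0.21, DDIT3 at 0.24 ± 0.23, CD14 at 0.16 ± 0.09, TLR4 at 0.01 ± 0.12 and ATF4 at 0.09 ± 0.09.

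In B27+LPS over C, 21 of 30 cytokine and chemokine genes rose and 9 did not pass (27 rose adjusted over the list alone). The median was 1.38 (adjusted p = 5.74e-40, and adjusted p = 0.00214 with an estimated correlation). Of 33 NF-kB targets 15 rose and 18 did not pass (17 rose adjusted over the list alone), with a median of 0.47 (adjusted p = 2.88e-16, and adjusted p = 0.0327 with an estimated correlation). ICAM1 rose by 1.57 ± 0.09, TRAF1 by 1.42 ± 0.13 and NFKBIA, the NF-kB inhibitor, by 1.33 ± 0.14. Of 36 interferon-stimulated genes 7 rose and 29 did not pass (16 rose and 1 fell adjusted over the list alone). The list's median was 0.21 (adjusted p = 5.03e-06, but adjusted p = 0.346 with an estimated correlation, and fry adjusted p = 0.02495). EIF2AK2 rose by 0.60 ± 0.09, IFIT1 by 0.77 ± 0.14, OASL by 1.23 ± 0.23 and USP18 by 0.57 ± 0.11.

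Among the other lists in B27+LPS over C, MMP12 (1.46 ± 0.21), CD163 (1.45 ± 0.25) and S100A8 (0.53 ± 0.12) rose of 30 macrophage markers, and S100A9 stood at 0.78 ± 0.21. MT2A (1.93 ± 0.21) and TXNRD1 (0.94 ± 0.22) rose of 12 oxidative stress genes, with HMOX1 at -0.67 ± 0.19 and MT1G at 0.54 ± 0.16. PFKFB3 (1.38 ± 0.10) and ADM (0.37 ± 0.07) rose of 20 hypoxia genes, with SLC2A3 at 0.28 ± 0.09 and PGAM1 at -0.26 ± 0.16. Single members passed in 4 lists, and these were chosen after their values were seen: DNAJC3 (0.46 ± 0.09), ATF3 (1.95 ± 0.15), TLR2 (1.42 ± 0.17) and SREBF2 (0.40 ± 0.09) rose. None of these lists passed camera as a whole, and the lowest adjusted p of the remaining lists was 0.0913, for the oxidative stress and the cell cycle list. By fry the oxidative stress list (adjusted p = 0.00584, median 0.17) and the LPS receptor list (0.0457, median 0.07) passed. With replicate number as a block the oxidative stress list had camera adjusted p = 0.0215, and the cell cycle and myeloid progenitor lists 0.0398. Without replicate 8 the cell cycle list had 6.46e-04 and the oxidative stress list 0.0232, and without replicate 6 the latter had 0.0384.

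In B27+LPS over C 600 features passed, 454 up and 146 down (75.7% up), and 141 changed by over 1 log2. With the pairing of replicates as a block 1178 passed. The count was 72 without replicate 6 and 167 without replicate 9, 61 with only the comparison's own arrays, and 200 or 915 with only the arrays whose numerator was in Cy3 or Cy5. Of 37 named genes that passed, 14 kept their call whichever replicate was left out.

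Within B27 cells, LPS (B27+LPS over C minus B27 over C) raised CCL4 by 4.74 ± 0.14, SOD2 by 4.41 ± 0.16, CCL1 by 3.75 ± 0.48, IL1B by 3.73 ± 0.32, CCL8 by 3.65 ± 0.30, CCL20 by 3.35 ± 0.14, CCL3 by 3.24 ± 0.26, CXCL10 by 3.23 ± 0.24 and MMP3 by 2.77 ± 0.33 (log2, n = 3). OLR1, a receptor for oxidized lipoprotein, rose by 2.61 ± 0.42. IL10 rose by 2.46 ± 0.18 and TNF by 1.79 ± 0.30 (adjusted p = 0.0221), and IL6 stood at 1.64 ± 0.35 (adjusted p = 0.0727). Of 25 named genes that passed, 8 kept their call whichever replicate was left out. The call of TNF is lost without replicate 6 (adjusted p = 0.3915), 8 (0.107) or 9 (0.193). GPR34 (-2.25 ± 0.34), EVI2B (-1.70 ± 0.30), CD244 (-1.58 ± 0.28) and KBTBD11 (-1.48 ± 0.27) fell. Falls were also found for the serine protease gene HTRA1 (-1.03 ± 0.19), GLO1, glyoxalase (-0.88 ± 0.17), TMEM216 (-0.76 ± 0.13), COA3, an assembly factor of cytochrome oxidase (-0.67 ± 0.11), the sialic acid receptor SIGLEC7 (-0.60 ± 0.11) and FCMR, the IgM receptor (-0.58 ± 0.09). B2M stood at 0.36 ± 0.19, XBP1 at 0.31 ± 0.14, HSPA5 at -0.03 ± 0.30, DDIT3 at -0.05 ± 0.33, ATF4 at 0.04 ± 0.12, CD14 at 0.24 ± 0.13 and TLR4 at -0.06 ± 0.16.

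In the LPS response of B27 cells 15 of 30 cytokine and chemokine genes rose and 15 did not pass (22 rose adjusted over the list alone, median 1.46). The list had adjusted p = 4.18e-44, and adjusted p = 0.00214 with an estimated correlation. Of 33 NF-kB targets 10 rose and 23 did not pass (16 rose adjusted over the list alone, median 0.47), with adjusted p = 3.42e-21, and adjusted p = 0.0184 with an estimated correlation. ICAM1 rose by 1.63 ± 0.13, TRAF1 by 1.44 ± 0.19 and TNIP1, an inhibitor of NF-kB signalling, by 1.46 ± 0.22. Of 36 interferon-stimulated genes 0 passed (6 rose adjusted over the list alone). The list, with a median of 0.32, had adjusted p = 1.00e-10 but adjusted p = 0.183 with an estimated correlation, and fry adjusted p = 0.0235. IFIT1 stood at 0.97 ± 0.20, EIF2AK2 at 0.62 ± 0.13, OASL at 1.48 ± 0.33 and IFIT3 at 1.54 ± 0.38. With the pairing of replicates as a block these 4 passed (adjusted p = 0.00495 for IFIT1, 0.0121 for EIF2AK2, 0.0179 for OASL and 0.0156 for IFIT3). ATF3 (1.81 ± 0.22), TLR2 (1.39 ± 0.24), MMP12 (1.55 ± 0.30), MT2A (2.09 ± 0.30) and PFKFB3 (1.30 ± 0.15), chosen after their values were seen, rose as the only called member of their list. No other list passed camera or fry, the lowest camera adjusted p being 0.149 for the cell cycle, which had 0.0451 with the replicate block and 0.0122 without replicate 8. The oxidative stress list had 0.0232 without replicate 8.

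The LPS response of B27 cells held 131 features past the threshold, 116 up and 15 down (88.6% up), and 228 with the pairing of replicates as a block. The count was 21 without replicate 6, 20 without replicate 9, 30 with arrays scaled to equal spread and 25 with only the arrays whose numerator was in Cy3. In the main fit, which takes the groups as independent, the difference of 2 groups carries a larger error (median 0.15 log2 against 0.10). Fewer features here than in C+LPS over C therefore does not show a smaller response. The 2 groups correlated by replicate number, at 0.364, 0.511 and 0.362 in replicates 6, 8 and 9. The unpaired error can thus be too large for this difference, and the pairing block, with 228, takes the shared part out.

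Without LPS, B27 cells and control cells did not differ past the threshold for any gene. The smallest p-values belonged to YEATS2, a subunit of a histone acetyltransferase complex (0.23 ± 0.05 log2, n = 3), CDC123, which helps assemble a translation initiation factor (0.46 ± 0.12), OAS2, an interferon-induced oligoadenylate synthetase (-0.61 ± 0.16), the ubiquitin ligase UBE3A (0.48 ± 0.13) and the ER lectin MLEC (0.30 ± 0.08). Each had adjusted p = 0.982, and a second probe of UBE3A stood at 0.09. HSPA5 stood at 0.26 ± 0.21 with replicate values of -0.11, 0.78 and 0.11, DDIT3 at 0.29 ± 0.23 with 0.00, 0.93 and -0.06, XBP1 at 0.07 ± 0.10 and ATF4 at 0.05 ± 0.09. TNF stood at -0.17 ± 0.22, IL6 at -0.08 ± 0.25, IL10 at 0.26 ± 0.13, IL1B at 0.08 ± 0.23, B2M at 0.10 ± 0.14, TLR4 at 0.07 ± 0.12 and CD14 at -0.09 ± 0.09.

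The interferon-stimulated list was lower in B27 cells by camera, with a median of -0.12 and 29 of 36 members below 0 (adjusted p = 6.80e-04, but adjusted p = 0.519 with an estimated correlation, and fry adjusted p = 0.377). It had adjusted p = 0.557 on arrays whose numerator was in Cy3. 0 of its members passed, also adjusted over the list alone, with OAS2 as above, IFI35 at -0.13 ± 0.06, IRF9 at -0.15 ± 0.09 and OAS3 at -0.15 ± 0.09. The ER chaperone list had a median of 0.05 (adjusted p = 0.215), the cytokine list -0.03 (0.910) and the class I presentation list -0.04 (0.891). The cytosolic heat shock list had fry adjusted p = 0.0457 and camera adjusted p = 0.775, with a median of 0.07. No list other than the interferon-stimulated one passed camera, the next lowest adjusted p being 0.198 for epithelial markers (median -0.03).

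limma called 0 of 18547 features in B27 over C, with 456 at unadjusted p under 0.05, and the methods' t-test called 0 after adjustment and 465 without it. Without any difference a share of 0.05 of the features would lie under that p. Both 456 and 465 are below this share, so they do not point to genes that differ. A count below the share can also mean that the share does not hold for these p-values. The counts therefore do not show that no gene differs either. With only the arrays whose numerator was in Cy3 or Cy5, 5 or 48 passed. The 5 were SEC24D (2.01 log2) and 4 probes without a gene symbol, chosen after their values were seen, and 1 dye orientation cannot separate a gene from its dye effect.

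After LPS, B27 cells set directly against control cells again held no gene past the threshold. OAS2 had the smallest p, at -1.07 ± 0.16 log2 (adjusted p = 0.447, replicate values -1.16, -1.10 and -0.95, n = 3). MOBP, a myelin protein gene, stood at -0.28 ± 0.06, the adenylyl cyclase ADCY3 at -0.38 ± 0.08, CHERP, an ER calcium protein, at -0.29 ± 0.07 and VPS9D1 at -0.42 ± 0.10, each with adjusted p = 0.932. TNF stood at -0.40 ± 0.22, IL1B at -0.37 ± 0.23, IL10 at 0.29 ± 0.13, IL6 at 0.00 ± 0.25, B2M at 0.24 ± 0.14 and DDIT3 at 0.29 ± 0.23. HSPA5 stood at -0.18 ± 0.21, XBP1 at -0.13 ± 0.10, TLR4 at 0.11 ± 0.12, CD14 at 0.05 ± 0.09 and ATF4 at -0.04 ± 0.09. The NF-kB list was lower by camera, with a median of -0.06 (adjusted p = 0.0276, but adjusted p = 0.682 with an estimated correlation), and 0 of 33 members passed. IER3, an early response gene, stood at -0.68 ± 0.26, ICAM1 at -0.17 ± 0.09, NFKB2 at -0.21 ± 0.11 and the kinase MAP3K8 at -0.17 ± 0.09. That list call is lost without replicate 6 (adjusted p = 0.721, median -0.06) or 8 (0.0777, median -0.08), with only numerator Cy3 (0.118, median -0.11) or Cy5 (0.358, median -0.10) arrays and with a scan-day block (0.0551, median -0.06). The cytokine list had a median of 0.00 (adjusted p = 0.910), the ER chaperone list -0.05 (0.247) and the interferon-stimulated list -0.02 (0.920, 1 member, OAS2, fell adjusted over the list alone).

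limma called 0 of 18547 features in B27+LPS over C+LPS, with 876 at unadjusted p under 0.05, and the methods' t-test called 0 after adjustment and 1163 without it. Against the share of 0.05 that would be found without any difference, 876 lies below and 1163 above. The 2 tests part on the same values, so the counts do not settle whether genes differ. With a model of the RNA sources 1 feature passed, OAS2 (-1.13, adjusted p = 0.0165), chosen after its value was seen. With 24 arrays and a dye term 2 passed, OAS2 (adjusted p = 0.0305) and a probe without a symbol.

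For the difference between the B27 effect with and without LPS, the smallest p-values belonged to NOL3, an apoptosis repressor (0.52 ± 0.12 log2), INTS10, an Integrator subunit (-0.33 ± 0.08), YEATS2 (-0.30 ± 0.08), the kinase CLK3 (-0.53 ± 0.14) and CDC123 (-0.63 ± 0.16), none past the threshold (adjusted p = 0.999, n = 3). TNF stood at -0.22 ± 0.30, IL6 at 0.08 ± 0.35, IL10 at 0.03 ± 0.18, IL1B at -0.45 ± 0.32, HSPA5 at -0.43 ± 0.30, XBP1 at -0.20 ± 0.14, DDIT3 at 0.00 ± 0.33, B2M at 0.13 ± 0.19, ATF4 at -0.08 ± 0.12, TLR4 at 0.04 ± 0.16 and CD14 at 0.13 ± 0.13. The ER chaperone, folding and ERAD list was lower by camera, with a median of -0.11 (adjusted p = 0.0389, but adjusted p = 0.425 with an estimated correlation), and 0 of 25 members passed. SEC61B stood at -0.46 ± 0.21, SERP1 at -0.24 ± 0.11, the ER lectin chaperone CALR at -0.54 ± 0.27 and SEL1L, an ERAD adaptor, at 0.20 ± 0.12. The call is lost without replicate 6 (adjusted p = 0.323, median -0.09), 8 (0.129, median -0.07) or 9 (0.0519, median -0.14), on numerator Cy3 (0.286, median -0.06) or Cy5 (0.0547, median -0.17) arrays alone, without the dim chip (0.0518, median -0.105) and without both doubtful chips (0.0541, the same median). The ribosomal list, a check of RNA quality, also lay below 0, with a median of -0.10 and a mean of -0.13 (adjusted p = 0.134, 0.0398 with the replicate block and 0.0232 without replicate 8).

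limma called 0 of 18547 features for the interaction, with 474 at unadjusted p under 0.05, and the methods' t-test called 0 after adjustment and 719 without it. From the arrays against C alone the interaction again called 0, with 308 at unadjusted p under 0.05. Each of 474, 719 and 308 is below the share of 0.05 of the features that would be found without any difference. As for B27 over C, this does not show that no gene differs. The direct comparison and the difference of the arrays against C did not differ past the threshold for any feature by limma (0 called, 339 at unadjusted p under 0.05, also below that share). Across features these estimates correlated at only 0.186, and the median error of their difference was 0.18 log2. The 0 calls therefore do not show that the estimates agree. By camera, in tests chosen after the data were seen, 3 lists were higher in the direct comparison, the cytokine list (median of the difference 0.21, adjusted p = 1.78e-04, but adjusted p = 0.341 with an estimated correlation), the hypoxia list (0.07, 0.0245, but 0.216) and the NF-kB list (0.10, 0.0457, but 0.596). Of the cytokine list 15 of 30 members lay below 0 in the direct comparison and 24 in the difference of the arrays against C. Without replicate 8 the 3 lists had adjusted p = 0.395, 0.395 and 0.929 (medians 0.04, 0.04 and 0.02), without replicate 9 the hypoxia and NF-kB lists had 0.238 (medians 0.08 and 0.06), and on numerator Cy5 arrays alone the 3 lists had 0.854, 0.530 and 0.854 (medians -0.08, 0.06 and -0.06). The hypoxia list had 0.172 on numerator Cy3 arrays (median 0.16), and the NF-kB list 0.0952 with median centring (median 0.05), 0.0782 with the scan-day block (median 0.10) and 0.0503 without the dim chip (median 0.08). The interferon-stimulated list (median of the difference 0.05, adjusted p = 0.0540) had 0.0296 with the replicate block, 0.0346 without replicate 9, 0.0124 without the chip with bright empty spots and 0.0107 without both doubtful chips. Without replicate 6 the B cell markers had 0.0194, and on numerator Cy3 arrays the heat shock list had 0.0480, both below 0.

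**Figure D2:**
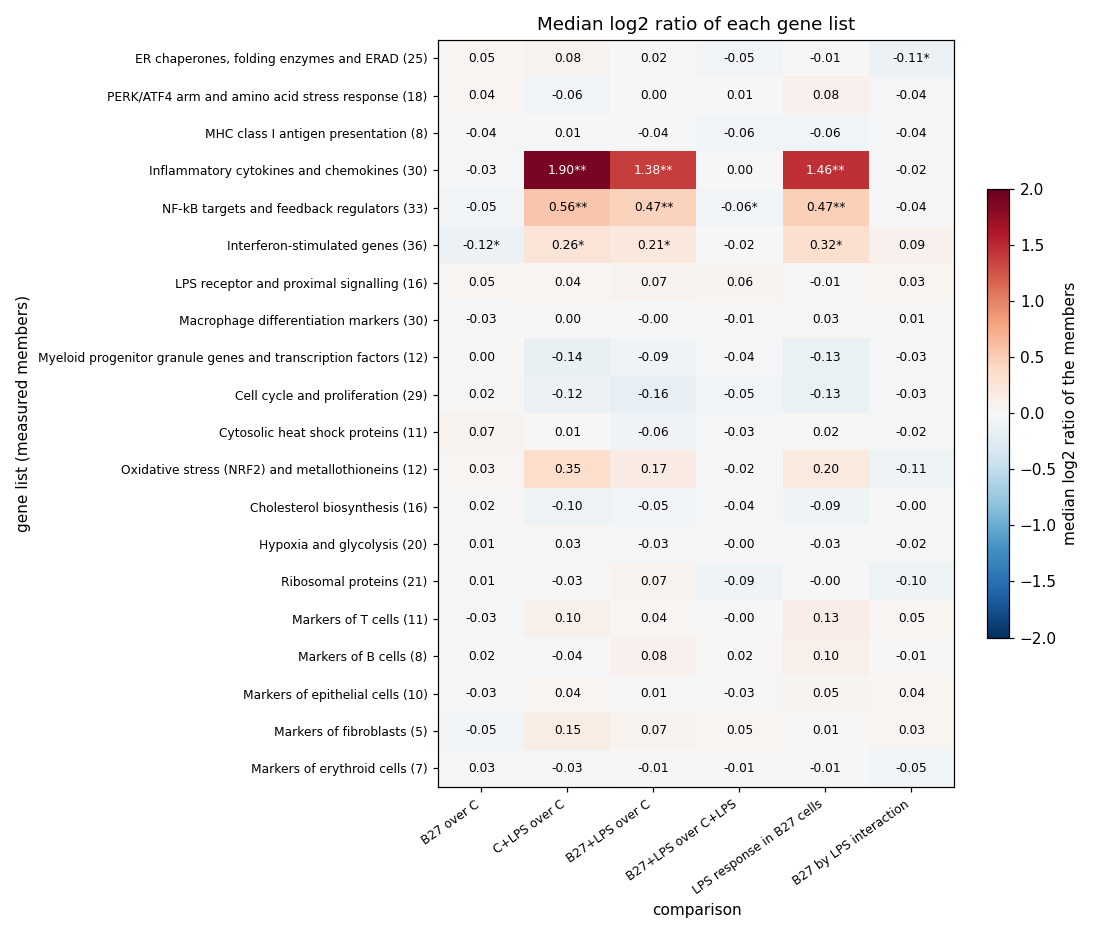
Median log2 ratio of the members of 20 gene lists in 6 comparisons, as a heat map. A star marks a camera adjusted p under 0.05 and 2 stars mark calls that hold with an estimated correlation, which are the cytokine list (medians 1.90, 1.38 and 1.46) and the NF-kB list (0.56, 0.47 and 0.47) in the comparisons with LPS.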

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

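The list test below was planned, and its replicate medians were computed only after the result was seen. The ER chaperone, folding and ERAD list is given here because it passed camera in the test of the difference between the B27 effects with and without LPS (adjusted p = 0.0389, 25 members, median -0.11), but it had adjusted p = 0.425 with an estimated correlation and 0.323 without replicate 6, 0.129 without 8 and 0.0519 without 9. The list medians of replicates 6, 8 and 9 were 0.01, 0.11 and 0.01 in B27 over C and -0.13, -0.04 and -0.04 in B27+LPS over C+LPS. HSPA5 stood at -0.43 ± 0.30 and CALR at -0.54 ± 0.27, and 0 members passed. The ribosomal protein list, a check of RNA quality, lay below 0 as well (median -0.10, mean -0.13, adjusted p = 0.134, and 0.0232 without replicate 8), so RNA quality stays open. The interaction also sets arrays of different scan days against each other on chip 1, so scan day stays open too. No biological explanation was tested.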

How the results depend on the processing

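The scan-day block, the settings without doubtful chips, the model of RNA sources for the lists and the B27 difference over both conditions were chosen after seeing the data. Each dye orientation alone was planned for single features, and its use for the lists was chosen after seeing the data. With only numerator Cy5 arrays the cytokine and NF-kB lists reversed in the direct comparison minus the difference of the arrays against C (medians -0.0797 and -0.0609). No other result reversed among those that passed in the main analysis or in the alternative. A change of sign was not counted where neither value passed. For example, the heat shock list in that difference had a median of -0.005 in the main analysis and 0.226 on numerator Cy5 arrays. Counts for C+LPS over C, B27+LPS over C and the LPS response in B27 cells (1060, 600 and 131) stayed within 1.5 times with median centring (933, 497 and 126), print-tip loess (1306, 840 and 185), the value table (967, 541 and 114) and without both doubtful chips (1328, 697 and 154). The same holds for the offset, dim probes, low confidence and all probes. With arrays scaled to equal spread the LPS response fell to 30. The methods' t-test called 0 in these 3 after adjustment, and unadjusted 1682, 1867 and 2220, with 465 for B27 over C, 1163 for B27+LPS over C+LPS and 719 for the interaction. With only a comparison's own arrays the counts were 132, 61 and 56, by construction with fewer arrays for the error. The RNA-source model gave 1781, 1813 and 288, and 24 arrays with a dye term 1665, 1241 and 309, which count arrays of a pair or paths of the loop as more information. These gave 1 and 2 for B27+LPS over C+LPS, and 1 and 2 for the B27 difference over both conditions, where the main analysis has 0. Leaving out each replicate, with fewer samples, gave 187 to 1151, 72 to 660 and 20 to 119. With only numerator Cy3 arrays the counts were 5 for B27 over C, 200 for B27+LPS over C, 4 for B27+LPS over C+LPS (SEC24D, H1-1 and 2 probes without a symbol, chosen after their values were seen), 25 for the LPS response and 5 for the B27 difference over both conditions. With only numerator Cy5 arrays they were 48, 915, 16, 148 and 58. The cause was not tested for the equal spread and dye settings.

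With the replicate numbers as a pairing block the counts were 1695, 1178 and 228, with the scan-day block 2594, 1994 and 450, and both blocks left 0 where the main analysis has 0. Of 120 list tests 12 passed, 6 with an estimated correlation, 19 with the replicate block and 20 with the scan-day block. The interferon-stimulated and ribosomal lists of the interaction passed camera with the replicate block (adjusted p = 0.0232 and 0.0398) and the scan-day block (0.0248 and 0.0113). With the scan-day block the oxidative stress list of the interaction passed too (0.0165). The interferon-stimulated list also passed on numerator Cy5 arrays alone (0.00346, median 0.16). The replicate numbers pair the arrays of the interaction only weakly. Of 113 calls of named genes 113 were kept with either block, 112 with the RNA-source model, 106 with median centring, 80 with equal spread, 74 and 90 with a single orientation and 49 without replicate 6. Of 92 named values without a call 12 passed with the replicate block and 14 with the scan-day block, among them SEC61B in C+LPS over C (adjusted p = 0.0137 and 0.00383), B2M (0.00472 and 0.00734) and XBP1 (0.0320 and 0.0144) in B27+LPS over C and IFIT1 in the LPS response of B27 cells (0.00495 and 0.00923), chosen after their values were seen. Signal over background limits the dimmest probes. Where dim probes were left out, 101 of the 101 calls that could be tested were kept, and the other 12 of 113 rest on probes left out there.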

Other observations

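The tests of the interferon and cytokine patterns and of OAS2 below were chosen only after the results were seen, and the tests over sign patterns and splits were planned. OAS2, which encodes an interferon-induced oligoadenylate synthetase, was the gene with the smallest p for the mean B27 difference over both conditions (-0.84 ± 0.11 log2, below 0 in 6 of 6 replicates, adjusted p = 0.184). In control cells it rose with LPS (0.72 ± 0.16, adjusted p = 0.0196), and in B27+LPS over C it stood at -0.53 ± 0.16 (adjusted p = 0.102). With a model of the RNA sources the mean difference was -0.87 (adjusted p = 0.0222), and OAS2 was then the only gene past the threshold.

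SEC24D, a coat protein of vesicles that leave the ER, stood at 1.78 ± 0.11 log2 for the mean B27 difference on arrays with the numerator in Cy3. It stood at -0.07 ± 0.15 in B27 over C and 0.06 ± 0.15 in B27+LPS over C+LPS when both orientations were averaged. It was chosen after its values were seen.

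The interferon-stimulated list lay below 0 in B27 over C. Its members may vary together between replicates. The correlation estimated for the list was 0.139, and with it camera gave adjusted p = 0.519. The list then also lost its calls in C+LPS over C (0.199), B27+LPS over C (0.346) and the LPS response of B27 cells (0.183). By fry it passed in these 3 (adjusted p = 0.00521, 0.02495 and 0.0235), but not in B27 over C (0.377). A lost call alone therefore does not show that shared variation is the cause. A dye effect of a probe that is the same on all arrays cancels in the pair means. The list median was -0.0574 on numerator Cy3 arrays and -0.108 on numerator Cy5 arrays. A lasting difference between the B27 and control transfectants is neither shown nor excluded. In B27+LPS over C+LPS 2 of 3 replicates had a list median below 0, but all lay near 0 (0.009, -0.048 and -0.037 in replicates 6, 8 and 9). There 19 of 36 members lay below 0, and camera gave adjusted p = 0.920.

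The cytokine list had a median of 1.90 in C+LPS over C and 1.38 in B27+LPS over C. The median difference of its members was -0.06, -0.53 and -0.10 in replicates 6, 8 and 9 (mean -0.23 ± 0.15, and -0.08 without replicate 8). A narrower range of ratios on the B27+LPS arrays could account for part of this, since falling features had smaller changes there as well (ratio of changes 0.951, 0.902 and 0.892 in the 3 replicates). Rising features, which include cytokine genes such as CCL4, had a lower ratio in each replicate (0.893, 0.775 and 0.864). The shrinkage of the falling features would give -0.08, -0.22 and -0.15, which covers the difference in replicates 6 and 9 and leaves -0.31 in replicate 8. What is left has a mean of -0.0773 ± 0.12, so a narrower range is neither shown nor excluded as the whole cause. An earlier form of this test asked only for ratios below 1, which were found, and was replaced after its values had been seen. A weaker cytokine response of B27 cells cannot be told apart from this, because the direct comparison had a mean list median of 0.00508 while the arrays against C gave the values above. The direct value lies within 2 standard errors of the other when both spreads are counted. That bound was revised after the value had been seen, and with the error of the direct medians alone (0.00709) the value would have counted against a weaker response.

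For the 4 comparisons with 3 replicates there are 4 sign patterns, and for the LPS response and the interaction 10 splits, too few for a share under 0.05. The real counts were 1060, 600 and 131 for the LPS comparisons, reached by 1 pattern each, with 0 as the highest other. For B27 over C and B27+LPS over C+LPS the real count was 0, reached by all 4 patterns, with 0 and 1 as the highest other, and for the interaction 0, reached by all 10 splits. A real count of 0 is reached by every pattern or split whatever the data, so these results carry no information. For the LPS counts, turning or moving a replicate puts a steady change into the error, so low counts elsewhere were likely in advance.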
